A study of Mus musculus with 6 samples.

How the data were processed

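Total RNA of 10,000 sorted green fluorescent leukaemia cells per sample was labelled as biotinylated cDNA with the GeneChip WT PLUS kit, per the labels' protocols. The authors deposited 1 table of probe set intensity values for 6 arrays, on a linear scale as judged from the values, which were all positive with a maximum of 14719. Background correction, normalization and summarisation of the deposited intensity values are not given in the sources used here, so the normalization behind each value stays unknown. The close medians and quartiles of the arrays point to values already normalized between arrays. The median log2 intensity per array lay between 5.69 and 5.79. Signal near background compresses a fold change, and normalization between arrays can hide a change shared by most genes.

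Samples were grouped by the labels into WT and Evi1 Tg, with n = 3 each, and no array was left out of the main comparison. Probe sets were named through the platform's annotation, with symbols checked through Entrez identifiers in a RefSeq table of assembly GRCm38.p6, in which 23328 probe sets were found and 0 were renamed. Of 34351 probe sets, 23521 had 1 gene symbol, 1814 had several and 9016 had none in the annotation. Probe sets with several symbols or none stayed out of the gene table. Where a gene had several probe sets, as 1082 genes did, the one with the highest mean over all arrays was used, which left 22180 genes. Values were log2 transformed with no pseudocount and no filter on dim genes.

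Evi1 Tg was compared with WT by lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are Evi1 Tg minus WT on the log2 scale, with the moderated standard error (SE). For gene lists, camera of limma was run with a correlation preset at 0.01 over 44 lists with at least 5 measured genes, and again with the correlation estimated for each list. By the estimated correlation 0 lists passed. The rotation test fry, which asks whether the genes of a list move one way without comparing them with other genes, called 0 lists higher and 1 lower, and its test for changes in either direction called 16. These were not the same lists that camera called with the preset correlation. They left out G2 and mitosis (fry adjusted p = 0.215 for either direction) and S phase (0.316), and held the MLL-AF9 list (1.81e-04), which camera did not call. Reactome sets came from fgsea 1.28.0 and held 10 to 300 measured genes. Of 1395 listed symbols 1220 were measured. The list of replication-dependent histones had too few measured genes to be tested. Figures were drawn with matplotlib 3.10.9.

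The gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule took Mecom, the 12 largest rises and falls past the threshold with separate groups (where fewer than 5 passed, the 12 with the smallest p and separate groups), up to 4 passing members per direction of each described list or else the 2 with the smallest p, and Asns, its list, Hoxa9 and Meis1. Its picks by change or by p left out predicted genes, microRNAs, small nucleolar RNAs, and immunoglobulin, T cell receptor, olfactory and vomeronasal genes. The other called genes named below the largest falls (Igf2r, Cfb, Rgs2 and Ptger4), and members named beyond this rule, were chosen after their values were seen. Background was set by the 90th percentile of 69 measured genes of a list of genes silent in blood cells, and 10219 genes (46.1%) lay above it.

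The alternatives were quantile normalization, median centring, dim genes left out, eBayes with trend and robust settings, array weights, a replicate block, the mean over probe sets, all probe sets, a test without moderation, a 2-fold limit, an unadjusted p with a 1.5-fold limit, the other Mecom probe set, an estimated correlation, fry, and leaving out each array in turn. Averaging Evi1 Tg 1 and Evi1 Tg 2 into 1 sample was added after seeing the data. The procedure was tested on simulated data for the comparison of 3 with 3 arrays over 22180 genes, in which 200 genes were changed. It recovered 73% of genes changed 2-fold and 95% of those changed 4-fold, and called 10 unchanged genes. A shifted list in the simulation was called by camera with the preset correlation and missed with an estimated one (adjusted p = 0.149). Where genes vary independently, a call missed with an estimated correlation therefore does not exclude a shift. The simulated genes did vary independently, while genes of the real lists moved together by array. The simulation thus favours the preset correlation and cannot say how often it calls real lists wrongly.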

Results

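Gene expression was measured on 6 microarrays of mouse leukaemia cells, 3 from MLL-AF9 leukaemias of wild-type origin (WT) and 3 from MLL-AF9 leukaemias that carried an Evi1 transgene (Evi1 Tg). MLL-AF9 is a fusion oncogene that gives rise to acute myeloid leukaemia, and Evi1, a zinc finger transcription factor, is a product of the gene Mecom. The cells were sorted for green fluorescence, so that each array read total RNA of unfractionated leukaemia cells. The series title names EVI1 and metabolic reprogramming, and the single comparison of the design was Evi1 Tg against WT. The 6 arrays had median intensities of 51.6 to 55.4 over 34351 probe sets. Pearson correlations across genes lay between 0.978 and 0.992 within groups and between 0.972 and 0.985 across groups, where genes are not independent replicates. The number of arrays limits the precision of every value. An exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.10. The labels do not say whether the 3 arrays of a group came from separate animals, so p-values measure only the spread between these samples.

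The transgenic gene was examined at the outset. Mecom was close to background in both groups, with a mean intensity of 36.9 in WT and 38.6 in Evi1 Tg (log2 difference 0.064, SE 0.0892, n = 3 per group, limma adjusted p = 0.890). The other Mecom probe set read 31.1 and 30.1, a log2 difference of -0.048, and the exact two-sided permutation p was 0.4 for each probe set. For comparison, 90% of the 69 measured genes fixed as silent in blood cells had a mean below an intensity of 71.1. A transgene of another species or a partial one can escape these probes, and its form is not given in the sources used here. The Mecom values therefore neither bear out nor contradict the labels, and each direction below rests on the labels alone.

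Genes with lower signal in Evi1 Tg outnumbered those with higher signal. Eya1, a transcriptional co-activator with phosphatase activity, fell by 4.58 on the log2 scale (SE 0.169, n = 3 per group, limma with Benjamini-Hochberg adjusted p = 4.85e-04), from a mean intensity of 1322 to 55.3. Saa3, an acute phase serum amyloid protein, fell by 2.34 (SE 0.152) from 2064 to 408. Rnase2a, a ribonuclease of the eosinophil-associated family, fell by 2.92 (SE 0.320). The difference was -2.28 (SE 0.199) for Tfpi, an inhibitor of blood coagulation, and -2.30 (SE 0.231) for the tyrosine kinase Fer. The other genes among the 12 largest falls were Clec3a (-2.49), Nxpe5 (-2.41), Platr4 (-2.41), the zinc finger factor Sp9 (-2.38), the protocadherins Pcdhb2 (-2.18) and Pcdhb3 (-2.08), and Ano4 (-1.87). In 11 of these 12 the Evi1 Tg mean lay below the intensity of 71.1, so the size of the fall is bounded by background. Smaller falls past the threshold were those of Igf2r (-1.79), the receptor for mannose 6-phosphate and insulin-like growth factor 2, complement factor B (Cfb, -1.66), Rgs2 (-1.39), a regulator of G protein signalling, and Ptger4 (-1.11), a receptor for prostaglandin E2. The size of the Rgs2 fall depended on the setting, with differences from -1.42 to -0.70 over 14 alternatives. Pcdhb2, Pcdhb3 and Rnase2a belong to families of similar genes, and cross-hybridisation between members was not tested.

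With limma and a Benjamini-Hochberg adjusted p under 0.05, 23 of 22180 genes were lower in Evi1 Tg and 2 were higher. At an unadjusted p under 0.05 there were 1286 lower and 997 higher genes, against 1109 that chance alone would give in both directions together. The 3 arrays of one group all lay on one side of the other group for 14.6% of genes, where chance gives 10%. The counts depended on single arrays. Without WT 3 there were 173 lower and 383 higher genes, without WT 2 39 and 12, and without WT 1 8 and 0. Without Evi1 Tg 1 there were 7 lower and 0 higher genes, without Evi1 Tg 2 2 and 0, and without Evi1 Tg 3 25 and 5. Of the 25 called genes, 25 were also called without WT 3, 21 without WT 2, 8 without WT 1, 6 without Evi1 Tg 1, 2 without Evi1 Tg 2 and 12 without Evi1 Tg 3. Eya1 passed in all 14 alternatives that refitted limma's moderated test over genes, but a test without moderation called 0 genes in either direction, Eya1 included.

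Among genes with higher signal in Evi1 Tg, Mfng and S100a6 passed the test. Mfng, a glycosyltransferase that modifies Notch receptors, rose by 1.11 on the log2 scale (SE 0.119, n = 3 per group, limma adjusted p = 0.0326), from a mean intensity of 85.1 to 184. S100a6, a small calcium-binding protein, rose by 1.22 (SE 0.138, limma adjusted p = 0.0423), from 111 to 258. As fewer than 5 genes passed, the 12 with the smallest p and separate groups among the kinds of gene that the rule names are given, and the other 10 did not pass. Elovl6, which elongates fatty acids, had a log2 difference of 2.88 (SE 0.388, limma adjusted p = 0.0770). Kit, the receptor for stem cell factor, had a difference of 1.22 (SE 0.176, limma adjusted p = 0.0772), and the transcription factor Runx3 one of 1.04 (SE 0.125, limma adjusted p = 0.0559). The differences of the remaining genes were 0.89 for Zbed3, 0.66 for the nuclear pore protein Pom121, 0.69 for Caskin2, 0.67 for the cell cycle regulator E2f4, 0.57 for Banf1, 0.58 for Pcbp4 and 0.57 for Xylt1. The WT means of Elovl6 (58.7), Runx3 (66.9), Pcbp4 (70.9) and Xylt1 (53.1) lay below the background intensity of 71.1, as did both means of Caskin2 (43.1 and 69.4), so background bounds these differences. Mfng lost its call in 6 and S100a6 in 7 of the 14 alternatives with limma's moderated test over genes, and both lost it in the test without moderation. The losses included those without WT 1, without Evi1 Tg 1 and without Evi1 Tg 2, where no gene was called higher. The fit over all probe sets is not among the 14. It called 2 probe sets higher, of which 1 lay outside the gene table, so at most 1 of Mfng and S100a6 passed there.

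**Figure D1:**
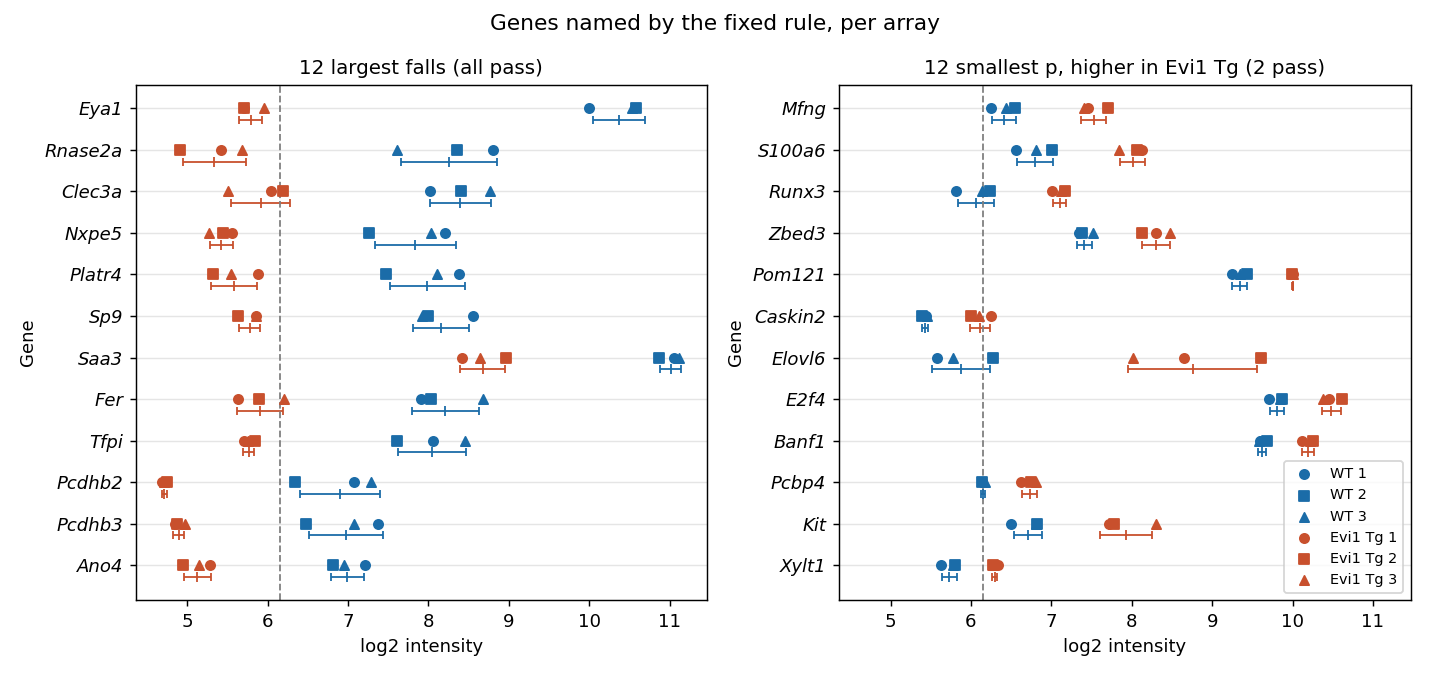
Log2 intensity of the genes named by the fixed rule (horizontal axis), 1 point per array, with WT in blue and Evi1 Tg in orange. The bar under each set of points gives the group mean and SD (n = 3), and the dashed line marks the intensity of 71.1 on the log2 scale (6.15). All 12 falls on the left passed the test, and Mfng and S100a6 on the right.

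Genes of cell division and DNA replication were higher as groups in Evi1 Tg. All 31 of 31 measured genes of G2 and mitosis had a difference above 0, with a median of 0.57 on the log2 scale (limma camera with a preset correlation, Benjamini-Hochberg adjusted p = 1.48e-13, and adjusted p = 0.551 with an estimated correlation). All 31 of 31 genes of S phase and DNA replication did so too, with a median of 0.55 (camera adjusted p = 2.56e-10, and adjusted p = 0.551 with an estimated correlation). Genes of nucleolar function and MYC targets had a median of 0.23, with 31 of 33 above 0 (camera adjusted p = 1.96e-07, and 0.551 as the adjusted p with an estimated correlation). Genes of purine and pyrimidine synthesis had a median of 0.28, with 22 of 25 above 0 (camera adjusted p = 1.08e-04, and adjusted p = 0.558 with an estimated correlation). No single member passed over all genes tested, and adjusted over the list alone 1 gene of G2 and mitosis passed and 0 of the other 3 lists. That gene was Foxm1, a transcription factor of mitotic genes, with a difference of 0.64 (SE 0.114, limma adjusted p = 0.136 over all genes). Cdc20, an activator of the anaphase-promoting complex, had 0.73 (SE 0.186), the polymerase subunit Pold1 0.72 (SE 0.172), the helicase subunit Mcm6 0.67 (SE 0.227), Polr1b 0.56, Nop2 0.34, Umps 0.66 and Impdh1 0.43, the last with a WT mean below background (60.1).

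Of 44 lists, camera with a preset correlation shifted 6 higher and 10 lower, against 0 and 0 with an estimated correlation (smallest adjusted p = 0.370) and 0 and 1 with fry. Without WT 3 the counts with the preset correlation were 9 and 16. WT 3 lay among the Evi1 Tg arrays in the lists of cell division and replication. The median deviation of the G2 and mitosis genes from their mean over the 6 arrays was -0.50 in WT 1, -0.68 in WT 2 and 0.33 in WT 3, against 0.25, 0.25 and 0.43 in Evi1 Tg 1, 2 and 3. For S phase genes it was -0.68, -0.54 and 0.33 in WT and 0.12, 0.36 and 0.28 in Evi1 Tg. For nucleolar genes and MYC targets WT 3 (0.18) also lay among the Evi1 Tg arrays (0.060, 0.20 and 0.11). For purine and pyrimidine synthesis WT 3 (0.31) lay above all Evi1 Tg arrays (0.069, 0.29 and 0.15), while WT 1 and WT 2 had -0.30 and -0.33. Without WT 3 the median difference was 0.87 for G2 and mitosis, 0.85 for S phase, 0.42 for nucleolar genes and MYC targets and 0.48 for purine and pyrimidine synthesis. Without WT 1 it was 0.35 for S phase and 0.14 for nucleolar genes, and without Evi1 Tg 1 it was 0.42 for purine and pyrimidine synthesis. The mitochondrial ribosome and chromatin regulators had small shifts upward, with medians of 0.071 and 0.13 (camera adjusted p = 0.00937 and 0.0360, and adjusted p = 0.689 and 0.370 with an estimated correlation). For the mitochondrial ribosome the deviation of WT 3 (0.15) lay above all Evi1 Tg arrays (0.051, 0.014 and 0.10). For chromatin regulators WT 3 (-0.020) lay below all of them (0.098, 0.051 and 0.015). For these lists 0 genes passed over all genes or adjusted over the list alone. Mrps2 had a difference of 0.48, Mrpl55 0.29, Ctbp2 0.30 and Arid1a 0.36. The adjusted p of the mitochondrial ribosome list was 0.311 without WT 1, 0.116 without WT 2 and 0.0912 without Evi1 Tg 3, and its median was 0.026 without WT 1 and 0.18 without WT 3. For chromatin regulators camera gave an adjusted p of 0.127 without WT 2, 0.108 without Evi1 Tg 1 and 0.0788 without Evi1 Tg 3, and one of 0.0509 with Evi1 Tg 1 and 2 averaged.

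Targets of p53 and apoptosis genes were lower as a group in Evi1 Tg. Their median difference was -0.35, with 16 of 20 genes below 0 (camera adjusted p = 1.96e-07, and adjusted p = 0.370 with an estimated correlation). No member passed over all genes, and 10 were lower adjusted over the list alone. Bcl2l11, which encodes the pro-apoptotic protein BIM, had a difference of -1.04 (SE 0.141) and Zmat3 one of -0.82 (SE 0.114), each with a limma adjusted p of 0.0772. The list's median deviation was 0.14, 0.061 and 0.28 in WT and -0.21, -0.11 and -0.10 in Evi1 Tg, so that all 3 arrays of each group lay on their own side. Antioxidant genes and NRF2 targets had a median of -0.25, with 17 of 21 below 0 (camera adjusted p = 1.51e-04, and adjusted p = 0.370 with an estimated correlation). Their deviations also separated the groups, at 0.12, 0.099 and 0.075 in WT and -0.10, -0.11 and -0.096 in Evi1 Tg, and this was the 1 list that passed fry, a rotation test (adjusted p = 0.00102). Adjusted over the list alone 2 of its genes were lower, Hmox1 (-1.26, SE 0.258), which encodes haem oxygenase 1, and malic enzyme Me1 (-1.13, SE 0.254), and 0 over all genes.

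Stress and nutrient lists were also shifted lower. Genes of the ATF4 and amino acid stress response had a median of -0.19, with 17 of 23 below 0 (camera adjusted p = 1.67e-04, and adjusted p = 0.370 with an estimated correlation). The mTORC1 and growth factor list had a median of -0.066, with 23 of 30 below 0 (camera adjusted p = 0.00140, and adjusted p = 0.370 with an estimated correlation), and the hypoxia list a median of -0.13, with 16 of 20 below 0 (camera adjusted p = 0.0119, and adjusted p = 0.473 with an estimated correlation). In each of them 0 genes passed over all genes, while adjusted over the list alone 3, 3 and 1 genes were lower. The leading members were shared, with Ddit4, an inhibitor of mTORC1 induced by stress, at -0.74 (SE 0.0932, limma adjusted p = 0.0595) in all 3 lists and Sesn2, a leucine sensor, at -0.94 (SE 0.134, limma adjusted p = 0.0772) in the lists of ATF4 and mTORC1. Both genes are known to restrain mTORC1. Pfkfb3, the other leading hypoxia gene, had -0.38 (SE 0.120). The hypoxia list had a camera adjusted p of 0.0633 without WT 1 and 0.114 with dim genes left out, and a median of -0.085 without WT 2. The median of the mTORC1 list was -0.11 without WT 1 and -0.12 without Evi1 Tg 1 or Evi1 Tg 3.

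Interferon response genes had a median of -0.29 in Evi1 Tg, with 34 of 40 below 0 (camera adjusted p = 1.97e-08, and adjusted p = 0.551 with an estimated correlation). Genes of inflammation and NF-kappaB had a median of -0.19, with 25 of 35 below 0 (camera adjusted p = 8.32e-05, and adjusted p = 0.551 with an estimated correlation). Over all genes 0 members of these lists passed, and adjusted over the list alone 7 interferon genes and 6 inflammation genes were lower. The chemokine Cxcl9 had a difference of -1.51 (SE 0.220), the RNA sensor Ddx58 -1.37 (SE 0.238), the apoptosis inhibitor Birc3 -0.46 (SE 0.101) and Ccrl2 -0.89 (SE 0.211). Part of these shifts came from WT 2, whose median deviation was 0.45 for interferon genes and 0.33 for inflammation genes. The interferon deviation of WT 3 (-0.11) lay close to those of Evi1 Tg 1 and 2 (-0.13 and -0.13). It was 0.11 in WT 1 and -0.31 in Evi1 Tg 3. For inflammation genes WT 1 and WT 3 had 0.013 and -0.012, against -0.27, -0.053 and -0.042 in Evi1 Tg 1, 2 and 3. Without WT 2 the medians were -0.19 and -0.11, and without Evi1 Tg 1 the inflammation median was -0.084. Genes of mast cells, basophils and eosinophils, cells that the sort could hold if they derive from the leukaemia, had a median of -0.16 (camera adjusted p = 0.0122, and adjusted p = 0.587 with an estimated correlation). In that list 0 genes passed over all genes, and adjusted over the list alone 1 was higher (Kit, 1.22) and 3 were lower, among them Mitf (-0.43, SE 0.0999). WT 2 also stood apart there with a deviation of 0.36, and without it the median turned to 0.0053 (camera adjusted p = 0.312). With dim genes left out the list was not called either (camera adjusted p = 0.173). That median was -0.10 without Evi1 Tg 1 and -0.097 without Evi1 Tg 2.

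**Figure D2:**
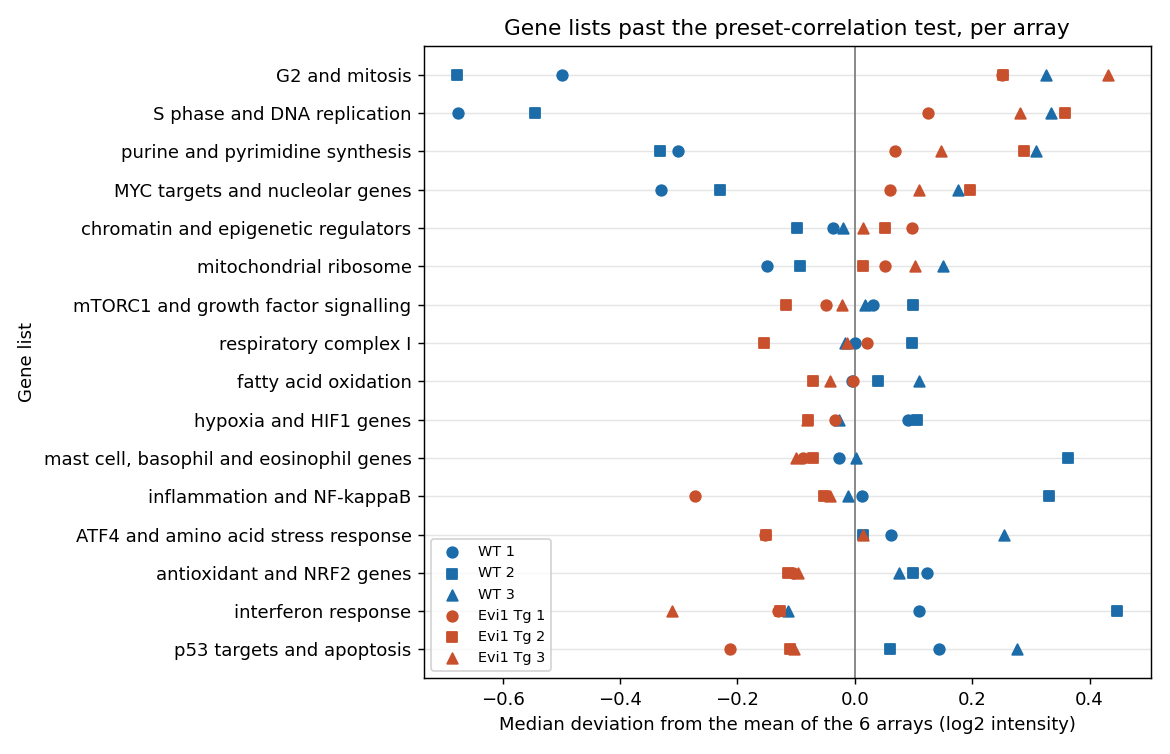
Median deviation of each gene list from its genes' mean over the 6 arrays (horizontal axis, log2 intensity), 1 point per array, for the 16 lists past camera with a preset correlation. WT is blue and Evi1 Tg is orange. WT 3 lies among the Evi1 Tg arrays for G2 and mitosis (0.33) and above all of them for purine and pyrimidine synthesis (0.31). For interferon genes WT 2 lies apart (0.45), and WT 3 (-0.11) lies close to Evi1 Tg 1 and 2 (-0.13 and -0.13).

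Metabolic genes, to which the series title refers, included Asns, the asparagine synthetase, which had a difference of -0.47 (SE 0.153, limma adjusted p = 0.353), from a mean intensity of 1640 to 1187. Of the 20 measured genes of asparagine, aspartate and glutamine metabolism, 10 lay above and 10 below 0 (median 0.00344, camera adjusted p = 0.950). Gpt2 (-0.40, SE 0.108), the glutamine synthetase Glul (-0.34, SE 0.0941) and the aspartate aminotransferase Got2 (0.31, SE 0.126) were the other members with an unadjusted limma p under 0.05, and 0 passed either over all genes or adjusted over the list alone. Genes of fatty acid oxidation had a median of -0.11 and those of respiratory complex I -0.10 (camera adjusted p = 0.0211 and 0.0360, and adjusted p = 0.370 and 0.558 with an estimated correlation). In both lists 0 genes passed over all genes or adjusted over the list alone. Acaa2 had a difference of -0.32, Acadm -0.38, Ndufc2 -0.51 and Ndufs4 -0.26. The list of fatty acid oxidation had a camera adjusted p of 0.120 without WT 3 and 0.0647 without Evi1 Tg 3, and complex I one of 0.312 without WT 2 and 0.506 without Evi1 Tg 2. Complex I was also lost with quantile normalization (adjusted p = 0.0816), dim genes left out (0.149), array weights (0.0891), the mean over probe sets (0.0621) and Evi1 Tg 1 and 2 averaged (0.0657), and held in 7 of 16 alternatives. Fatty acid oxidation was lost with dim genes left out (adjusted p = 0.120) and with array weights (0.0758). The median of complex I was -0.032 without Evi1 Tg 2 and -0.16 without Evi1 Tg 1, and that of fatty acid oxidation was -0.053 without WT 3.

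Other metabolic lists were not called by camera, and except for fatty acid synthesis 0 of their genes passed over all genes or adjusted over the list alone. Glycolysis had a median of -0.027 (adjusted p = 0.599), with Pfkfb3 at -0.38 and the lactate transporter Slc16a1 at 0.81 (SE 0.303). The citric acid cycle had a median of 0.012 (adjusted p = 0.928), with Idh2 at 0.35 and pyruvate carboxylase Pcx at -0.45. The adjusted p was 0.888 for ATP synthase, 0.0757 for respiratory complexes II to IV, 0.186 for the pentose phosphate pathway, 0.224 for mitochondrially encoded genes and 0.258 for mitochondrial biogenesis. It was 0.599 for amino acid transport, 0.0784 for serine and one-carbon metabolism and 0.759 for cholesterol synthesis. Fatty acid synthesis was not called either (adjusted p = 0.560), although adjusted over the list alone 3 of its genes were higher and 2 lower, with Elovl6 at 2.88 from a WT mean below background (58.7) and Me1 at -1.13. Cytosolic ribosomal proteins had a median of -0.025 (adjusted p = 0.796).

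Genes of the MLL-AF9 leukaemia program did not move together. Eya1 was the 1 member that passed over all genes, as of all the lists tested, and adjusted over the list alone 2 genes were higher and 1 lower. Hoxa9, a homeobox factor of this leukaemia, had a difference of -0.0196 (SE 0.162), its partner Meis1 0.85 (SE 0.265, limma adjusted p = 0.328) and Hoxa7 0.50 (SE 0.108, limma adjusted p = 0.195). The median of the list was 0.14 and its mean -0.043, and the camera test with its direction higher gave an adjusted p of 0.224. Among haematopoietic stem cell genes (camera adjusted p = 0.124), 3 were higher adjusted over the list alone and 0 over all genes, with Kit at 1.22 and the transcription factor Erg at 2.79 (SE 0.418, limma adjusted p = 0.0906) from a WT mean below background (60.7). The list of reported EVI1 targets had a median of -0.00437 and a mean of 0.021 (camera adjusted p = 0.804, direction higher). Adjusted over the list alone 1 of its genes was higher, Erg, and Id1 had a difference of 0.61 (SE 0.135).

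Lists of mature cell types were mostly not called. Granule proteins and neutrophil genes had a median of -0.26 (camera adjusted p = 0.258), while myeloperoxidase (Mpo) had a difference of 2.80 (SE 0.507, limma adjusted p = 0.139) and was the 1 gene higher adjusted over the list alone, and Elane had 0.44 (SE 0.131). The granule list varied between arrays, with a median deviation of 0.57 in WT 2 and -0.61 in Evi1 Tg 2. Monocyte and macrophage genes had a median of -0.075 (camera adjusted p = 0.111), with Tlr4 at -0.58 (SE 0.0908) and Adgre1 at -1.13 (SE 0.205), both lower adjusted over the list alone. The camera adjusted p was 0.0619 for B cell genes, 0.940 for T and NK cell genes, 0.950 for erythroid genes, 0.186 for megakaryocyte genes, 0.751 for dendritic cell genes and 0.224 for stromal and endothelial genes. Adjusted over the list alone, 2 B cell genes were lower, Igll1 (-0.61) and Bank1 (-1.27), 2 dendritic cell genes, Cst3 (-0.55) and H2-Ab1, and 4 stromal or endothelial genes, led by Igfbp7 (-1.25) and the endoglin gene Eng (-0.99), while 1 stromal gene was higher. For T and NK, erythroid and megakaryocyte genes this count was 0. Among signalling lists it was 0.186 for cytokine receptors, 0.251 for TGF-beta and BMP signalling, 0.224 for integrins and adhesion and 0.950 for immediate early and dissociation stress genes. Adjusted over the list alone, 3 integrin and adhesion genes were lower, led by Itga1 (-0.81) and Itgav (-0.78), 1 TGF-beta gene was higher and 2 were lower, 1 cytokine receptor was higher, and 0 immediate early genes passed. The Evi1 Tg means of Igll1 (61.9), Eng (59.9) and Itga1 (63.3) lay below background.

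Of 885 mouse Reactome pathways, 186 were shifted higher and 55 lower in Evi1 Tg by camera with a preset correlation, and 0 with an estimated correlation (smallest adjusted p = 0.746). Pathways can share genes, and some gave identical values, such as mRNA Splicing and its Major Pathway (109 genes and a median of 0.12 each). Neither these counts nor the pathways named below are therefore separate results. The 5 higher pathways with the smallest p all concerned mitosis, led by Mitotic Prometaphase with a median of 0.35 over 92 genes (camera adjusted p = 1.91e-09) and M Phase with 0.21 over 211 genes. The others were Resolution of Sister Chromatid Cohesion (0.35), Mitotic Metaphase and Anaphase (0.20) and Mitotic Anaphase (0.20). The lower ones were led by Negative regulators of RIG-I MDA5 signaling with a median of -0.21 over 20 genes (camera adjusted p = 2.32e-04) and Iron uptake and transport with -0.15 over 41 genes. Signaling by Interleukins (-0.090), the activation of IRF3 and IRF7 by TBK1 and IKK epsilon (-0.48) and the trafficking and processing of endosomal TLR (-0.19) followed. Without WT 2 there were 51 higher and 28 lower pathways, without WT 1 81 and 30, without Evi1 Tg 3 111 and 62, and without Evi1 Tg 2 199 and 35.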

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

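Probe sets outside the gene table were tested in the fit over all probe sets, which was planned. Of 10830 such probe sets, 1 was higher in Evi1 Tg than in WT, with a log2 difference of 0.94 (SE 0.0933, limma adjusted p = 0.0462, n = 3 per group) and mean intensities of 73.3 and 140. It was annotated to more than 1 gene and is therefore not named. Another 3 were lower, of which the largest fall was -2.96 (limma adjusted p = 0.0144), from 378 to 48.6, in a probe set with no gene in the annotation.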

How the results depend on the processing

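All alternatives here were planned except the averaging of Evi1 Tg 1 and 2, chosen after seeing the data. Counts are given as higher and lower genes in Evi1 Tg, against 2 and 23 in the comparison as reported. They were 6 and 26 with dim genes left out, 6 and 32 with trend and robust settings, 32 and 82 with array weights, 0 and 0 in the test without moderation, 201 and 372 at an unadjusted p with a 1.5-fold limit, and 0 and 6 with Evi1 Tg 1 and 2 averaged. Array weights gave WT 3 a weight of 0.455, the lowest. With quantile normalization they were 2 and 22, with median centring 2 and 28, with the mean over probe sets 2 and 23, with all probe sets 2 and 24, and with a 2-fold limit 2 and 21. The counts with all probe sets are of probe sets, and 1 higher and 3 lower of them lay outside the gene table. Leaving out each array gave 0 to 383 higher and 2 to 173 lower genes. The replicate block gave 0 higher and 9 lower genes, all 9 among the 25, and changed no list count (6 and 10). Deviations of arrays with the same number correlated at 0.189, -0.185 and 0.0614, not every array correlated best with its own number, and the numbers were not taken as pairs. The fixed lists, 6 higher and 10 lower as reported, were 8 and 6 with dim genes left out, 0 and 0 with an estimated correlation, 0 and 1 with fry, and 4 to 9 and 8 to 16 with each array left out. Reactome pathways, 186 and 55 as reported, were 175 and 35 with dim genes left out, 0 and 0 with an estimated correlation, and 51 to 267 and 28 to 62 with each array left out. Mecom was -0.048 in its other probe set, between 0.0074 and 0.11 with each array left out, and below the limit of the dim filter, which gave it, Pcdhb2, Pcdhb3 and Ano4 no value. Of the called lists, the median of mast cell, basophil and eosinophil genes turned from -0.16 to 0.0053 without WT 2. Among values that were not called, with each array left out Hoxa9 ran from -0.18 to 0.14 (0.06 with Evi1 Tg 1 and 2 averaged), the glycolysis list from -0.096 to 0.028, and the list of asparagine metabolism from -0.00654 to 0.0762. The dim filter and left-out arrays change the genes or samples tested, and for the other settings the cause was not tested. Signal over background limits the falls, since 11 of 23 ended below the intensity of 71.1.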

Other observations

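The tests of shared origin, of the Y-linked genes, of WT 3, of quantile normalization on the cell cycle genes, of chromosomes and of genes parted by over 2-fold, and the averaging of Evi1 Tg 1 and 2, were chosen after the result was seen, and so were the genes named here. In all, 4 genes were over 2-fold higher in every Evi1 Tg array than in every WT array. They were Hpgd, which breaks down prostaglandins (log2 difference 3.40, SE 0.640), Elovl6 (2.88, SE 0.388), Mpo (2.80, SE 0.507) and Erg (2.79, SE 0.418), and none passed limma's adjusted test (adjusted p = 0.148, 0.0770, 0.139 and 0.0906). In the other direction 23 genes were parted in this way, among them the forkhead factor Foxc1 (-1.49, SE 0.233, limma adjusted p = 0.0973), the anticoagulant protein S gene Pros1 (-2.36, SE 0.458, limma adjusted p = 0.162) and Mab21l2 (-3.36, SE 0.887, limma adjusted p = 0.253). The WT means of Elovl6 (58.7) and Erg (60.7) and the Evi1 Tg means of Foxc1 (49.2), Pros1 (45.2) and Mab21l2 (47.7) lay below the background intensity of 71.1, which bounds these differences.

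Some genes stood apart in a single array, with no enrichment test run on them. In WT 2, 29 genes were over 2-fold above all other arrays, among them the mast cell genes Cpa3, Hdc and Tpsb2, the neutrophil genes Ly6g, Cxcr2 and Mmp9, and the interferon genes Irf7, Usp18, Oasl2 and Zbp1. In Evi1 Tg 3, 8 genes were, among them the stefins Stfa2 and Stfa3. In Evi1 Tg 2, 18 genes were over 2-fold below all other arrays, among them the neutrophil genes S100a8, S100a9, Ngp and Cd177.

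Genes of cell division and replication were higher in Evi1 Tg by camera with a preset correlation (median 0.55 over the 62 genes of both lists), a call lost for each list with an estimated correlation (adjusted p = 0.551) and with fry (adjusted p = 0.404 and 0.428). A bias shared by genes of the same brightness is argued against, since 10000 random lists matched on mean level had medians within -0.071 to 0.072 for 95% of draws. An unequal spread left in the deposited values is argued against too, since the median was 0.56 after quantile normalization. The arrays already had close medians and quartiles, so this setting could change little and says nothing of the processing before deposit. Low values of WT 1 and WT 2 alone stay open: WT 3 lay below all 3 Evi1 Tg arrays for 11.3% of these genes, against 98.4% for WT 1 and 100% for WT 2, which restates the array values that raised the question and decides nothing. Whether the shift may reflect slower cycling in WT 1 and WT 2 or the transgene was not settled by these tests. For the called lists the real split of the arrays gave 16, and 3 of 10 splits, the real one included, gave as many, with up to 21 in another. For Reactome the real split gave 241, and 4 of 10, again with the real one, gave as many, with up to 325. The others among these splits set WT 1 and WT 2 together with an Evi1 Tg array. This points to a structure of the samples, although 10 splits are too few for a share under 0.05.

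Eif2s3y, a Y-linked gene, read a mean intensity of 36.5 in Evi1 Tg 1 and 2 and 661 in the other 4 arrays, a log2 difference of -4.18. A missing Y chromosome is argued against if the probe sets of Kdm5d and Uty read Y transcripts alone, since their mean differed by -0.15 between the same arrays. That condition was not tested. Over the arrays Kdm5d read 7.46 to 7.66 and Uty 7.88 to 8.51 on the log2 scale, so none showed that these probe sets can read low. A missing Y chromosome in Evi1 Tg 1 and 2 therefore stays open. Xist, a transcript of the inactive X chromosome, read 35.8 in Evi1 Tg 1 and 2 and 37.1 in the other 4 arrays. These values lay below the background intensity of 71.1, and no array showed that its probe set works. A shared origin of Evi1 Tg 1 and 2, such as 1 leukaemia clone, may account for it and stays open. With Eif2s3y left out, 21 genes parted this pair from the other arrays by over 2-fold, among them Cd34 and Satb1, against 13 at most for any of the other pairs among 15, but arrays that are alike for any reason would give such a count, so it does not bear out a shared origin. If they share an origin the group holds fewer independent samples than its n, in which case averaging them left 0 higher and 6 lower genes.

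Genes whose values in every array of one group lay over 2-fold above every array of the other numbered 27, of which 18 passed the test. The lower group was not always near background, as Hpgd had a WT mean of 428 and Ly6a2 an Evi1 Tg mean of 941. Some also varied within WT, as Erg and Hpgd were over 2-fold lower in WT 1 and WT 3 than in all other arrays. Of the 10 splits of the arrays 1, the real one, parted as many, and the highest of the others parted 3, while for called genes the real split gave 25 and the highest other 1. As 3 against 3 arrays make 10 splits, these are too few for a share under 0.05. A single chromosome segment carried by one group is argued against as the whole cause, since the 27 genes lay on 16 chromosomes with at most 4 on any one, while 0 pairs outside gene families lay within 10 genes of each other, which decides nothing because random draws also had a median of 0. A hypothesis that stays open, and was not tested, is that a difference in the founding cell or clone of each group may have set these genes, as may the transgene itself, whose signal these probes did not show.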
